A study of Mus musculus with 4 samples.

How the data were processed

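RNA labelled with 4-thiouridine (4sU), a uridine analogue that living cells build into the RNA they are making, was sequenced from mouse embryonic stem cells of the 129/Ola line. Per the labels' protocols, labelled RNA was coupled to biotin through biotin-HPDP, caught on streptavidin beads and turned into libraries with a Vazyme kit. The cells carried an auxin-inducible degron on SNRNP70, the U1-70K protein of the U1 small nuclear ribonucleoprotein (snRNP), and had received the auxin IAA for 0 h or for 5 h. The labels name the 0 h cells wild type although their titles give the degron line. Each time had 2 libraries. The labelling time and any spiked-in RNA were not given in the sources used here, so every change below is relative to the other RNAs of the same library.

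The deposited table held whole-number gene counts for the 4 libraries and 55401 genes. Per the submitters' processing notes, HISAT2 2.2.1, StringTie 2.2.1 and DESeq2 1.42.0 were used with the mm10 build, and the notes do not say which of them made the table. The values were treated as estimated counts, because per the file headers and row names the layout is that of StringTie's count export, and because in the deposited values 3 and 4 were each more frequent than 2 in every library. Such counts come from coverage, so 1 sequenced fragment can be worth several counts and counting error can be larger than the numbers imply. The annotation and the strand setting were not given in the sources used here. Reads from a gene and an overlapping or antisense partner, and from an intronic snoRNA and its host, therefore could not be told apart, and values of genes with near-identical copies (histones, ribosomal proteins, mitochondrial genes, U1 snRNA genes) are uncertain. The counts were already whole, so rounding changed nothing. All rows had a gene name, and no column of another sample was in the table.

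Total counts were 17752887 and 7174772 in the 0 h libraries (replicates 1 and 2) and 15645894 and 10349277 in the 5 h libraries. A floor of 3 counts corresponded to 0.169, 0.418, 0.192 and 0.290 CPM (counts scaled to a common library total) in the same order, covering counting error only. Gene symbols were matched to a RefSeq gene table of the GRCm38 assembly, to which mm10 corresponds. Of the 55401 genes, 39082 matched by symbol, 163 by synonym and 16156 did not match, and 217 shared a symbol with another gene. The table gave the gene class, the position and the span from start to end. A genome sequence and exon annotation were not used here, so single-exon genes, intron number, exon length and GC content were not analysed here.

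Genes were kept by filterByExpr with the groups, which left 17344. They were fitted in edgeR 4.0.16 with TMM factors (1.10, 1.10, 0.927 and 0.896 in the order above) and edgeR's quasi-likelihood test with robust estimation, 5 h minus 0 h, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The library means in CPM are TMM-normalised. Only this contrast exists in the design, and all 4 libraries entered the fit. The main design had no replicate block, and the fit with the replicate number as a block was an alternative. A fold against a group at 0 in both libraries is given against the mean of that group's floors, TMM-normalised like the means, as a lower bound.

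The 28 gene lists were fixed before the data were examined. The 27 lists with at least 3 tested members were tested with camera in limma 3.58.1 on log-CPM values with a prior count of 2 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 27 lists. Camera compares a list with all other tested genes. It was repeated with the correlation estimated from the data. That form takes its p from the residual degrees of freedom, few with 4 libraries in 2 groups, so it had little power to call any list. Fry tested whether the members of a list move, on balance, one way. Genes of a list were also adjusted over the list alone. Genes were named by a rule fixed before the data were examined. It takes Snrnp70 and Zfp207, the 12 genes with the highest and the 12 with the lowest log2 fold change among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups, and the 3 members of each list with the lowest adjusted p. Where no member of a list passed, its 2 members with the highest mean CPM were taken. Predicted genes, clone names and pseudogenes were left out of the top 12. They held 8 of the first 12 places among genes that rose and 5 of the first 12 among genes that fell. Some genes that the rule takes are not reported here. Genes named outside the rule are said to have been chosen after their values were seen.

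Gene length was the RefSeq span, known for 15098 of the 17344 tested genes (87.1%). Spearman's rho was computed across genes, which are not independent replicates, so no p is given for it. To set a list against gene length, its median log2 fold change was ranked among the medians of 10000 random lists matched on 10 bins of length and 4 bins of expression.

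The tests were tried on simulated counts with the means and depths of these libraries and 2 libraries per group. In the simulated 5 h against 0 h comparison of 17344 genes, edgeR recovered 16% of 50 genes changed by 1.5-fold, 42% of 50 changed by 2-fold, 72% of 50 changed by 4-fold and 82% of 50 changed by 8-fold. It also called 17 of 17123 unchanged genes, which were 12.6% of its calls. Far more genes were called in the real data (3814 higher and 3677 lower), which makes the Benjamini-Hochberg adjustment less strict there. These shares therefore do not give the power or the error of the real fit. A list moved by 1.5-fold as a whole was called by camera with Benjamini-Hochberg adjusted p = 1.49e-16. Of the other 26 lists 0 was called. Simulated genes were drawn independently of each other and without a trend with length. In the real data the estimated correlation within a list reached 0.522, so the simulation does not measure camera's false calls there.

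The alternatives were other scalings (DESeq2's size factors, library totals, upper quartiles and the total over mitochondrially encoded genes), 2 other filters on low counts, DESeq2 1.42.0, limma-voom, the replicate block, fitting without robust estimation, leaving out each library in turn, leaving out the 20 most counted genes, and protein-coding genes alone. Counts divided by 4, and mitochondrially encoded genes left out, were added after seeing the data. Calculations ran in R 4.3.3, and figures were drawn with matplotlib 3.10.9.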

Results

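The series asked how loss of SNRNP70, the U1-70K protein of the U1 snRNP, compares with loss of the zinc finger protein ZFP207 in its effect on U1 snRNP function. The data used here cover the SNRNP70 arm. Newly made, 4sU-labelled RNA was measured in mouse embryonic stem cells whose SNRNP70 carried an auxin-inducible degron, which lets auxin send the tagged protein to the proteasome. There were 2 libraries from cells without auxin (0 h) and 2 from cells given auxin for 5 h, with totals from 7174772 to 17752887 counts. The series text calls them 2 independent replicates, and nothing in the labels says that they came from separate cultures. If they did not, the p-values measure only the spread between these samples, which can be technical. Replicate libraries correlated across genes at r = 0.969 (0 h) and 0.965 (5 h) on log CPM, and libraries of different groups at 0.906 to 0.931. The median absolute log2 difference was 0.19 between the 0 h libraries, 0.24 between the 5 h libraries and 0.59 between the group means.

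After 5 h of auxin, labelled RNA of short genes, splicing regulators, ribosomal proteins, snoRNA host genes and immediate early genes was higher relative to the other genes. Labelled RNA of long genes and of DNA repair genes was lower. Of 17344 tested genes, 3814 rose and 3677 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1318 and 1764 of them by 2-fold or more. The split between higher and lower genes depended on the scaling. Scaling to library totals gave 2297 higher and 5257 lower genes, and scaling to the mitochondrially encoded genes gave 396 and 8872. The median log2 fold change of all tested genes was -0.02 with TMM, -0.28 with library totals and -0.86 with mitochondrial scaling, so all changes are given relative to the median gene of the TMM fit. With TMM and with both other scalings, camera called the SR protein, hnRNP, ribosomal protein, snoRNA host, immediate early and DNA repair lists relative to the other genes. Camera's Benjamini-Hochberg adjusted p ran from 1.46e-18 to 0.00294. A scaling shifts all genes nearly alike and camera compares genes with each other, so the same calls under each scaling add little support. With an estimated correlation, a form with little power at 4 libraries, camera called none of these lists (adjusted p = 0.231 to 0.548). Low power was not the only difference. The estimated correlation was 0.437 for hnRNPs, 0.124 for DNA repair and 0.068 for SR proteins, against the preset 0.01. For these lists the p with the preset can be too small. For the other lists called it ran from -0.045 to 0.028. Mitochondrially encoded genes took 4.41% and 4.34% of the counts at 0 h and 6.03% and 7.17% at 5 h.

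Labelled Snrnp70 RNA rose, from 246 ± 4.46 CPM at 0 h to 463 ± 17.3 CPM at 5 h (SD, n = 2 each). Its log2 fold change was 0.91 ± 0.09 (SE), or 1.88-fold, with adjusted p = 3.69e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 0.06 with mitochondrial scaling. The degron acts on the protein, so this RNA does not check the labels. Snrnp70 lies on chromosome 7 from 45376454 to 45395742 (mm10). Zfp207, on chromosome 11 from 80383279 to 80408561, rose from 576 ± 40.5 to 953 ± 77.8 CPM. Its log2 fold change was 0.73 ± 0.09 (edgeR, Benjamini-Hochberg adjusted p = 0.000180). With mitochondrial scaling it was -0.13 and did not pass.

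**Figure D1:**
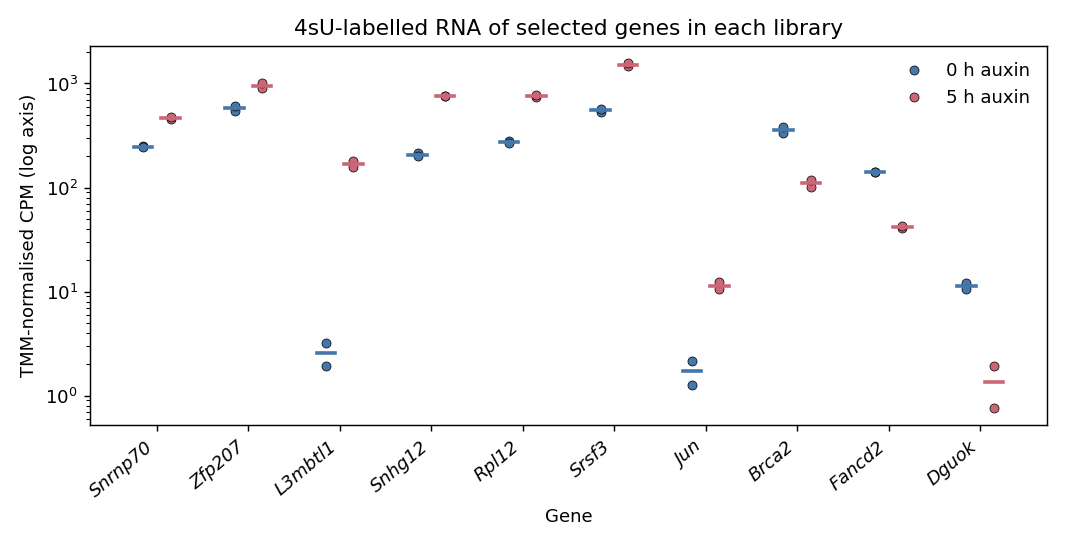
TMM-normalised CPM (log axis) of 10 named genes in each of the 4 libraries, with points for libraries and bars for the mean of the 2 libraries at 0 h (blue) and at 5 h (red). L3mbtl1 lies at 2.55 CPM at 0 h and 169 CPM at 5 h on average, and Fancd2 at 141 and 41.8 CPM. Zfp207, higher at 5 h here, has a log2 fold change of -0.13 and is not called when libraries are scaled to mitochondrially encoded genes.

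Among single genes, L3mbtl1, which encodes a chromatin-compacting MBT domain protein, rose 61.0-fold, from 2.55 ± 0.907 to 169 ± 14.0 CPM (SD, n = 2). Its log2 fold change was 5.93 ± 0.19 with adjusted p = 1.78e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. L3mbtl1 spans 162942333 to 162977806 on chromosome 2, next to the SR protein gene Srsf6. Its counts at 0 h, 62 and 15, were the same as those of Mir3535 on chromosome 1 in both libraries, for a reason not known here, and its 0 h level and fold are uncertain to that extent. Togaram2, which encodes a TOG domain protein, rose by 4.67 ± 0.40 on the log2 scale, and Cmya5, a muscle gene, by 3.33 ± 0.33. Trim72, which encodes a membrane repair protein of muscle, rose from 6.82 ± 0.978 to 53.4 ± 5.87 CPM. Slc25a47 (3.13), Sdcbp2 (3.02), Mir3535 (2.99), Snord92 (2.97) and Adam1b (2.52) were also among the 12 named genes with the highest log2 fold changes, as were the chaperone gene Hspa1a (2.76) and the AP-1 gene Jun (2.64). Naip1, an inflammasome sensor with near-identical copies, had a log2 fold change of 5.34 ± 0.80, but DESeq2 did not call it (Benjamini-Hochberg adjusted p = 0.0830, the highest of 18 alternatives, of which the lowest was 7.87e-23). It had 0 and 6 counts at 0 h, and its log2 fold change was 3.72 without 0 h replicate 1. Without 0 h replicate 2 it had no count left at 0 h, so no fold is given. Without 0 h replicate 1 the value was 3.88 for Slc25a47 and 3.44 for Hspa1a.

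Among genes that fell, Dguok, the mitochondrial deoxyguanosine kinase, went from 11.4 ± 1.03 to 1.35 ± 0.832 CPM (SD, n = 2), a log2 fold change of -3.00 ± 0.40 with adjusted p = 0.000212 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Trmu, which modifies mitochondrial tRNAs, changed by -2.75, Dus4l, a dihydrouridine synthase, by -2.57, and Alg8, a glucosyltransferase of N-glycosylation, by -2.53. The receptor gene Notch3 fell from 53.2 ± 6.43 to 9.75 ± 2.62 CPM. Ccdc191 (-2.87), Qsox2 (-2.73), Ece2 (-2.35), Nadsyn1 (-2.29), Lyrm9 (-2.26), Nipsnap2 (-2.25) and Lrrc29 (-2.24) completed the 12. Ece2 had 43 and 5 counts at 5 h, and was at -4.13 without 5 h replicate 1 and at -1.68 without 5 h replicate 2. Without 5 h replicate 1 Dguok was at -3.90 and Dus4l at -3.46. All 12 stayed lower with library totals and with mitochondrial scaling. Both of these move the median gene downward, so this outcome was fixed in advance.

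Gene length was examined because U1 snRNP is known to keep long genes from being cut and polyadenylated early. The 3031 tested genes under 5 kb had a median log2 fold change of 0.49, which was 0.23 with library totals and -0.34 with mitochondrial scaling, and 975 of them rose and 142 fell. With library totals 683 rose and 248 fell, and with mitochondrial scaling 168 rose and 597 fell. The median was -0.00 for 4657 genes of 5 to 20 kb, -0.21 for 3761 of 20 to 50 kb, -0.28 for 1933 of 50 to 100 kb and -0.29 for 1716 over 100 kb. Of the genes over 100 kb, 159 rose and 512 fell. With library totals these were 57 and 748, and with mitochondrial scaling 4 and 1194. Across 15098 genes Spearman's rho between log2 fold change and length was -0.297, and it lay between -0.245 and -0.306 in the 4 pairs of a 5 h with a 0 h library. Between replicate libraries it was -0.0841 at 0 h and -0.0878 at 5 h. With mitochondrial scaling the median of the genes under 5 kb changed sign, and those of the other 4 classes stayed below 0.

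**Figure D2:**
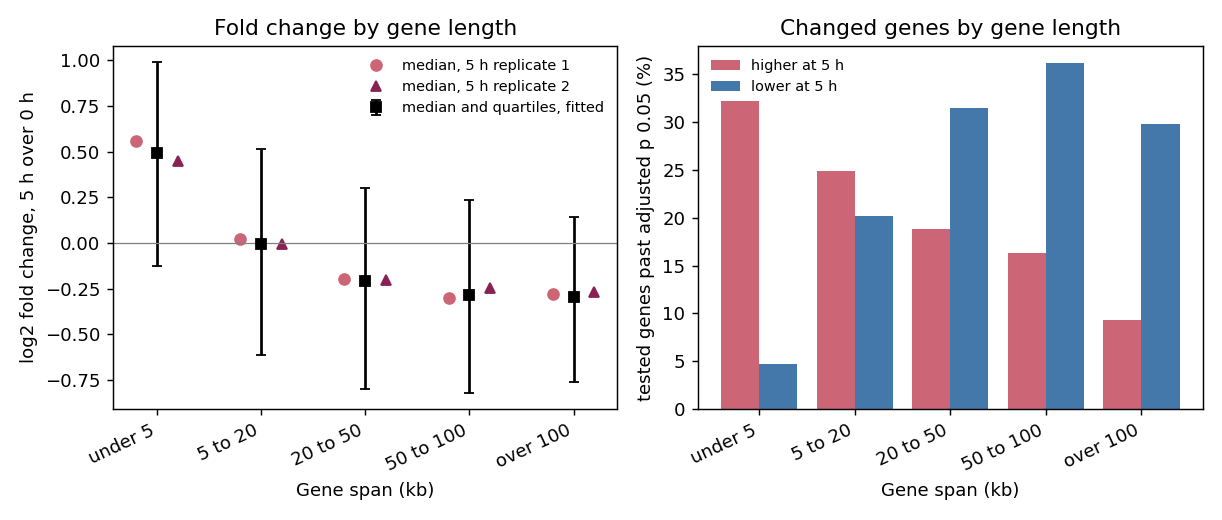
Left, log2 fold change (5 h over 0 h) by gene span in kb, with squares and bars for the median and quartiles of all tested genes of a class and coloured points for the medians of each 5 h library against the 0 h mean. Right, percent of tested genes of the class past adjusted p 0.05 in each direction. The median falls from 0.49 under 5 kb to -0.29 over 100 kb, and with mitochondrial scaling from -0.34 to -1.13, where all 5 classes lie below 0.

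Splicing regulators rose as groups relative to the other genes. Of 21 SR proteins and their kinases, which bind exonic enhancers and help define exons, 18 rose, 1 fell and 2 did not pass, and 18 and 1 did so when adjusted over the list alone. Their median log2 fold change was 0.92, and 0.07 with mitochondrial scaling, where 4 rose and 4 fell. Srsf3 rose from 551 ± 24.7 to 1519 ± 68.8 CPM (log2 1.46 ± 0.09), Tra2a by 1.51 ± 0.10 and Srsf7 by 1.28 ± 0.09. For this list camera gave Benjamini-Hochberg adjusted p = 2.06e-06, and adjusted p = 0.371 with an estimated correlation. Of 28 hnRNPs, proteins that coat nascent RNA, 23 rose and 2 fell (24 and 2 adjusted over the list alone), with a median of 0.79 that became -0.08 with mitochondrial scaling, where 2 rose and 8 fell. Hnrnpl rose by 1.27 ± 0.08, Hnrnph1 by 1.25 ± 0.10 and Hnrnpdl by 1.13 ± 0.10. The hnRNP list had Benjamini-Hochberg adjusted p = 4.91e-06 by camera, and adjusted p = 0.548 with an estimated correlation of 0.437. No list called by camera was past the threshold with an estimated correlation.

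Genes of the U1 snRNP and its partners also tended upward with TMM. Of 15 genes, 10 rose and 2 fell, also when adjusted over the list alone, and the median of 0.50 became -0.36 with mitochondrial scaling, where 0 rose and 8 fell. Besides Snrnp70 they included the other U1-specific proteins, Snrpc (1.05 ± 0.10) and Snrpa (0.97 ± 0.10). The U1 list had Benjamini-Hochberg adjusted p = 0.0400 by camera, and adjusted p = 0.667 with an estimated correlation of 0.369. That call was lost with library totals, mitochondrial scaling, the stricter count filter, counts divided by 4, and without 0 h replicate 1 (adjusted p = 0.127) or 5 h replicate 2 (adjusted p = 0.117), and over 17 alternatives tested by camera the adjusted p ran from 0.0161 to 0.667. Of 20 genes of the U2 snRNP and U2AF, which recognise the branch point and 3' splice site, 11 rose and 1 fell, over all genes and adjusted over the list alone. Their median was 0.43 with TMM and -0.42 with mitochondrial scaling, where 0 rose and 11 fell. Puf60 rose by 1.06 ± 0.12, Dhx15 by 0.85 ± 0.09 and Sf3b3 by 0.66 ± 0.08, and the last 2 had negative values with mitochondrial scaling. The U2 list had Benjamini-Hochberg adjusted p = 0.0104 by camera and adjusted p = 0.394 with an estimated correlation. It was not called with library totals, mitochondrial scaling or without 0 h replicate 1 (adjusted p = 0.0589, 0.555 and 0.0508), in a range from 0.00285 to 0.555 over the same alternatives.

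Other parts of the spliceosome moved both ways. Of 23 tested genes of the U4/U6.U5 tri-snRNP, 11 rose and 5 fell, over all genes and adjusted over the list alone (the median of 0.27 was -0.58 with mitochondrial scaling), with Sart1 at 1.28 ± 0.10, Snu13 at 0.82 ± 0.10 and Snrnp200 at 0.74 ± 0.10. Of 20 genes of the Sm core and its assembly machinery, 8 rose and 5 fell, with the same counts when adjusted over the list alone and a median of 0.09 that became -0.75 with mitochondrial scaling. The Sm proteins Snrpe (1.37 ± 0.11) and Snrpd2 (1.24 ± 0.15) rose, and Gemin4, of the SMN complex that loads Sm proteins onto snRNA, fell by 1.17 on the log2 scale. Camera called neither list (Benjamini-Hochberg adjusted p = 0.187 and 0.714). Fry, which tests a list against no change and not against other genes, called the tri-snRNP list (Benjamini-Hochberg adjusted p = 0.0134). None of the 8 tested spliceosomal snRNA genes passed by edgeR over all genes or adjusted over the list alone, 0 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 as well. Camera did not call the list (Benjamini-Hochberg adjusted p = 0.162), but did so in the fit with a replicate block (adjusted p = 0.0446). The U1 genes Rnu1b1 and Rnu1b2 had log2 fold changes of 0.42 ± 0.23 and 0.19 ± 0.17. Rnu1b1 passed with a log2 fold change of 0.67 without 0 h replicate 1 and of 0.73 without 5 h replicate 2, where the list was called as well (adjusted p = 0.0196).

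**Figure D3:**
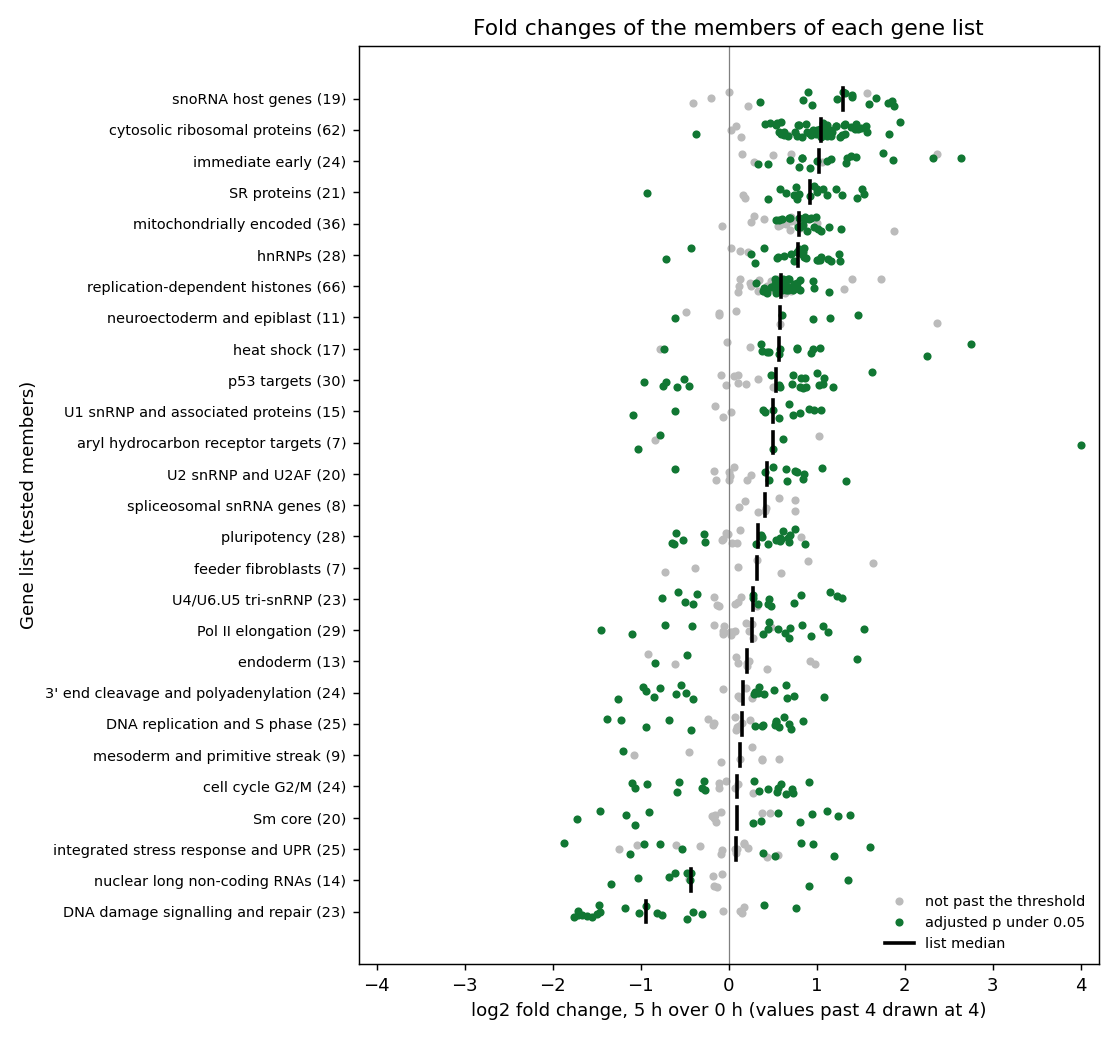
Log2 fold change (5 h over 0 h) of each tested member of 27 gene lists, with members past adjusted p 0.05 in green, the others in grey, the list median as a black bar and the number of tested members in parentheses; 1 value past 4 is drawn at 4. Medians run from -0.94 for DNA damage and repair to 1.30 for snoRNA host genes, and mitochondrial scaling makes them -1.78 and 0.46 and leaves a median above 0 for SR proteins, immediate early genes, ribosomal proteins and snoRNA hosts alone.

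Genes acting on transcription and on 3' ends gave mixed lists. Of 29 genes of RNA polymerase II elongation, 12 rose and 4 fell (13 and 4 adjusted over the list alone). Hexim1, an inhibitor of the elongation kinase P-TEFb, rose from 136 ± 5.59 to 392 ± 44.7 CPM, and Supt5 (1.07 ± 0.09) and Leo1 (1.13 ± 0.10) rose too. The list median of 0.26 became -0.01 with library totals and -0.60 with mitochondrial scaling, where 1 rose and 17 fell. By camera the list had Benjamini-Hochberg adjusted p = 0.0400, and adjusted p = 0.414 with an estimated correlation. The call was also lost with both scalings, the stricter filter, counts divided by 4 and without either 0 h replicate (adjusted p = 0.134 and 0.0560), in a range from 0.0119 to 0.953 over the 17 alternatives. Of 24 cleavage and polyadenylation genes, 10 rose and 9 fell (camera, Benjamini-Hochberg adjusted p = 0.752). The poly(A)-binding gene Pabpn1 rose by 1.08 ± 0.10, and the cleavage factor genes Cstf2 and Pcf11 changed by -1.26 ± 0.12 and -0.85 ± 0.10. The counts were 10 and 9 when adjusted over the list alone, and the median of this list was 0.16, its mean -0.04 and its median -0.69 with mitochondrial scaling.

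Genes of cytosolic ribosomal proteins and of snoRNA hosts were higher. Of 62 tested cytosolic ribosomal protein genes, 57 rose and 1 fell, over all genes and adjusted over the list alone. Their median was 1.05, and 0.20 with mitochondrial scaling, where 14 rose and 5 fell. Rpl12 rose from 274 ± 4.86 to 760 ± 23.5 CPM, and Rpl41 by 1.57 ± 0.10 on the log2 scale. Camera gave Benjamini-Hochberg adjusted p = 7.17e-16, and adjusted p = 0.231 with an estimated correlation. Of 19 tested snoRNA host genes, whose introns carry snoRNAs, 14 rose, also when adjusted over the list alone, and 5 did not pass. The host list had a median of 1.30, and of 0.46 with mitochondrial scaling, where 8 rose and 5 fell. Snhg12, on chromosome 4 from 132308678 to 132311024, rose from 207 ± 8.82 to 759 ± 8.55 CPM, and Snhg16 and Snhg1 rose by 1.86 ± 0.10 and 1.59 ± 0.10. The hosts had Benjamini-Hochberg adjusted p = 8.44e-06 by camera, and adjusted p = 0.371 with an estimated correlation.

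Replication-dependent histone genes, which have no introns and end without a poly(A) tail, rose modestly. They rose less than random lists matched on length and expression, whose median was 0.83 (percentile 0). Of 66 genes, 42 rose (43 adjusted over the list alone) and 24 did not pass, and the median of 0.60 became -0.23 with mitochondrial scaling. With library totals 17 rose and none fell, and with mitochondrial scaling 0 rose and 4 fell. H4c4 rose by 0.97 ± 0.10, and H2ac10 (0.73 ± 0.09) and H2bc18 (0.62 ± 0.08) rose with TMM and had negative values with mitochondrial scaling. The histones had Benjamini-Hochberg adjusted p = 5.09e-08 by camera, and adjusted p = 0.571 with an estimated correlation. Fry gave adjusted p = 0.0953. Of 36 mitochondrially encoded genes, 20 rose (21 adjusted over the list alone), with a median of 0.79. They included mt-Atp8 (1.05 ± 0.08), mt-Cytb (0.91 ± 0.09) and mt-Nd4l (0.89 ± 0.08), and their median was -0.06 when they were themselves the scale. The mitochondrial list had Benjamini-Hochberg adjusted p = 1.89e-06 by camera, adjusted p = 0.571 with an estimated correlation, and adjusted p = 0.0815 by fry.

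DNA damage signalling and repair genes were lower. Of 23 tested genes, 17 fell, 2 rose and 4 did not pass, and the counts were the same when adjusted over the list alone. The median was -0.94, -1.21 with library totals and -1.78 with mitochondrial scaling. Fancd2, which the Fanconi anaemia pathway loads at DNA crosslinks, fell from 141 ± 0.748 to 41.8 ± 1.41 CPM (log2 -1.76 ± 0.11). Its partner Fanci changed by -1.61 ± 0.11, and Brca2, which acts in homologous recombination, by -1.71 ± 0.11, from 358 ± 28.6 to 109 ± 12.4 CPM. Brca2 lies on chromosome 5 from 150522297 to 150570147. The repair list had Benjamini-Hochberg adjusted p = 0.000360 by camera, and adjusted p = 0.414 with an estimated correlation. Of 25 DNA replication genes, 11 rose and 5 fell (12 and 6 adjusted over the list alone), among the latter Pole (-1.22 ± 0.09), Rfc1 (-1.38 ± 0.11) and Mcm6 (-0.94 ± 0.11). Of 24 G2/M genes, 10 rose and 8 fell (11 and 8 adjusted over the list alone), with Ube2c at 0.91 ± 0.11, Nusap1 at -1.07 ± 0.13 and Ttk at -0.93 ± 0.12. Camera called neither cell cycle list (Benjamini-Hochberg adjusted p = 0.400 and 0.656). Their medians of 0.15 and 0.09 were -0.68 and -0.75 with mitochondrial scaling. With library totals 5 replication genes rose and 8 fell, and with mitochondrial scaling 0 rose and 17 fell. For G2/M genes the counts were 6 and 10, and 0 and 16.

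Immediate early, heat shock and p53 target genes were higher relative to the other genes. Among random lists matched on length and expression, immediate early genes lay at percentile 100 and p53 targets at 97.9. Heat shock genes lay at 60.1, so they rose about as much as matched genes. Of 24 tested immediate early genes, 18 rose (20 adjusted over the list alone), and the median was 1.03, and 0.17 with mitochondrial scaling, where 6 rose and 2 fell. Myc rose from 119 ± 7.28 to 268 ± 2.14 CPM, Ier2 by 1.34 ± 0.11 and Ccn2 by 1.33 ± 0.12. The immediate early list had Benjamini-Hochberg adjusted p = 3.29e-07 by camera, and adjusted p = 0.371 with an estimated correlation. Of 17 heat shock genes, 13 rose and 1 fell, over all genes and adjusted over the list alone, with Hspa1b at 2.25 ± 0.19, Dnajb1 at 0.96 ± 0.10 and Ahsa1 at 0.93 ± 0.09. The heat shock median of 0.57 became -0.29 with mitochondrial scaling, where 2 rose and 7 fell (camera, Benjamini-Hochberg adjusted p = 0.00171, adjusted p = 0.0844 with mitochondrial scaling, and adjusted p = 0.371 with an estimated correlation). Of 30 targets of the tumour suppressor p53, 16 rose and 6 fell (17 and 6 adjusted over the list alone). Plk2 rose by 1.63 ± 0.09, Mdm2, the ligase that degrades p53, by 1.19 ± 0.09 and Sesn2 by 1.07 ± 0.10. The p53 median of 0.54 became -0.30 with mitochondrial scaling, where 1 rose and 11 fell and which also ended the call (camera, Benjamini-Hochberg adjusted p = 0.0110, and adjusted p = 0.414 with an estimated correlation). The integrated stress response list was split, with 6 of 25 genes rising and 5 falling, over all genes and adjusted over the list alone, among them Ddit4 (1.60 ± 0.14), Hspa5 (0.95 ± 0.08) and Pck2 (-1.87 ± 0.20). Its median was 0.08, and -0.75 with mitochondrial scaling, and its mean -0.05 (camera, Benjamini-Hochberg adjusted p = 0.792).

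Indole compounds such as auxin can bind the aryl hydrocarbon receptor, and of 7 tested targets of this receptor 3 rose and 2 fell, over all genes and adjusted over the list alone. Their median of 0.50 became -0.35 with mitochondrial scaling. Lrrc58 (0.62 ± 0.09) and Tiparp (0.50 ± 0.10) rose with TMM and had negative values with mitochondrial scaling, and the antioxidant regulator Nfe2l2 changed by -0.79 ± 0.11. Tiparp was not called with library totals (0.23). The receptor's classical target Cyp1a1, chosen after its values were seen, had 0 counts in both 0 h libraries and 21 and 8 counts at 5 h, at least 4.32-fold higher by group means in TMM-normalised CPM, against a 0 h floor of 0.268 CPM from 3 counts per library (edgeR, Benjamini-Hochberg adjusted p = 0.0126). It was tested in 14 of 17 other settings and called in 12 of them. Edc3, 4.72 kb from Cyp1a1, had 81.8 CPM at 0 h, and transcription running on from it could not be separated from that of Cyp1a1. Camera did not call the receptor list (Benjamini-Hochberg adjusted p = 0.573), and fry did (adjusted p = 0.0348).

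Genes of cell state showed no list past camera's threshold. Of 28 pluripotency genes, 14 rose and 6 fell, over all genes and adjusted over the list alone. Sox2 was at 0.86 ± 0.10, Stat3 at 0.75 ± 0.09 and the demethylase gene Tet1 at -0.60 ± 0.08. The median of 0.34 became -0.51 with mitochondrial scaling, where 0 rose and 17 fell. With library totals 8 rose and 8 fell. The pluripotency list had Benjamini-Hochberg adjusted p = 0.109 by camera, and adjusted p = 0.0410 in the fit of protein-coding genes alone, in a range from 0.0410 to 0.953 over the 17 alternatives tested by camera, and fry gave adjusted p = 0.0307. Of 11 tested neuroectoderm and epiblast genes, 4 rose and 1 fell, over all genes and adjusted over the list alone, with Zic2 at 1.15 ± 0.22 and Pou3f1 at 0.96 ± 0.19, and the median of 0.59 became -0.27 with mitochondrial scaling. Of 9 tested mesoderm genes 1 fell, Kdr, at -1.20 ± 0.39, which did not pass when adjusted over the list alone, by DESeq2, or without any 1 of the 4 libraries. Of 13 tested endoderm genes, Col4a1 rose (1.45 ± 0.37, and 2.34 without 0 h replicate 1), and Lama1 (-0.84 ± 0.10) and Sparc (-0.48 ± 0.12) fell, also when adjusted over the list alone. The mesoderm list had a median of 0.13 and a mean of -0.12, and the endoderm list a median of 0.21, which became -0.71 and -0.64 with mitochondrial scaling. Of the 26 genes of the 2-cell-like list only Zscan4f was tested, and it did not pass (0.43 ± 1.16). Of 7 tested markers of feeder fibroblasts none passed by edgeR over all genes or adjusted over the list alone, 0 had an unadjusted p under 0.05, DESeq2 and limma-voom called 0 as well, and Thy1 and Col5a1 had 7.47 and 5.76 CPM at 0 h against 9.28 and 6.09 CPM at 5 h. Camera gave Benjamini-Hochberg adjusted p = 0.193, 0.792, 0.798 and 0.693 for neuroectoderm, mesoderm, endoderm and fibroblasts.

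Of 14 tested nuclear long non-coding RNAs, 7 fell and 2 rose, over all genes and adjusted over the list alone. Ftx, a transcript of the X-inactivation centre, fell from 55.7 ± 3.32 to 22.1 ± 1.34 CPM and Mirg from 106 ± 6.59 to 51.6 ± 6.97 CPM. Tsix rose from 133 ± 2.92 to 339 ± 5.55 CPM, and its antisense partner Xist overlaps it, so their reads could not be told apart without strand. The median of -0.43 was -1.28 with mitochondrial scaling, and camera gave Benjamini-Hochberg adjusted p = 0.0855, and fry adjusted p = 0.00903.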

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

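Counts divided by 4, and leaving out the mitochondrially encoded genes, were the only alternatives chosen after seeing the data. Of the named genes past the threshold, 96 in number, 1608 of 1616 results under the alternatives other than mitochondrial scaling kept direction and call, 8 lost the call (Kdr in 5, Naip1, Sparc and Tiparp in 1 each) and none reversed. Most of these genes were picked as the most extreme or lowest in adjusted p of the main fit, so their calls were likely to hold. Over all tested genes DESeq2 kept 3339 of the 3814 rises and 2908 of the 3677 falls. The scaling decided the direction for many genes. With library totals 2297 genes rose, 700 rose and 2814 fell by 2-fold or more, Rnu1b2 was at -0.076 and Col5a1 at -0.16. With mitochondrial scaling 396 rose and 8872 fell, 243 and 6378 by 2-fold or more, and 342 genes had the opposite call. Snrnp70 was then at 0.061, Zfp207 at -0.13, H2ac10 at -0.11, H2bc18 at -0.22, Dhx15 at -0.0052, Sf3b3 at -0.18, Snu13 at -0.038, Snrnp200 at -0.10, Rnu1b1 at -0.39, Rnu1b2 at -0.64, Stat3 at -0.095, Zscan4f at -0.36, Lrrc58 at -0.23, Tiparp at -0.35, Thy1 at -0.52 and Col5a1 at -0.72. These shifts follow from the factor itself, and which scale is right was not tested. The fit of protein-coding genes alone tested fewer genes, and 819 rose by 2-fold or more.

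List values here are the list median minus the median of all tested genes. The U1 list lost its call at 0.516 with library totals, 0.503 with mitochondrial scaling, 0.499 with the stricter filter, 0.510 with counts divided by 4 and 0.518 with an estimated correlation, and ranged from 0.429 to 0.673 with a library left out. The p53 list lost it at 0.559 with mitochondrial scaling and 0.554 with an estimated correlation, and the histones at 0.614 with an estimated correlation. The pluripotency list gained a call at 0.415 with protein-coding genes. Fry tests a list against no change and not against other genes, and it called the pluripotency list (median log2 fold change 0.335) and not the U1 list (0.502) or the histones (0.598). It also called the tri-snRNP, aryl hydrocarbon receptor and nuclear long non-coding RNA lists, which camera did not. Spearman's correlation of fold change with gene length was -0.186 without a filter, -0.335 with the stricter filter and -0.342 for genes with a mean of at least 5 CPM, and from -0.236 to -0.296 with a library left out. Values of low genes that did not pass reversed when a library was left out, with Zscan4f from -0.41 to 1.64 and Col5a1 from -0.23 to 0.37. The cause of these changes was not tested, apart from the scalings. With a replicate block 3837 genes rose and 3545 fell, and the spliceosomal snRNA list gained a call (0.447). The deviations of same-numbered libraries correlated at 0.0505 in only 2 pairs, so the numbers were not taken to pair the libraries. Leaving out a library leaves 1 in its group, which is then assumed to vary like the other group. Single-exon genes, intron number and summed exon length were not run, for want of an exon annotation here. In the simulated counts 16% of 1.5-fold changes were recovered, and depth was not varied. Far fewer genes changed there than were called in the real data, so this share does not give the power of the real fit.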

Other observations

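The tests in this part of expression level and of the immediate early genes were chosen after the result was seen, as were the groups of genes in the first 2 paragraphs. Within the Sm core list, 5 of 8 Sm proteins rose by edgeR's quasi-likelihood test, Snrpb (log2 fold change 1.11 ± 0.14, SE), Snrpd1 (0.94 ± 0.14), Snrpd2 (1.24 ± 0.15), Snrpe (1.37 ± 0.11) and Snrpd3 (0.37 ± 0.13), and Snrpf (0.47), Snrpg (0.38) and Snrpn (-0.14) did not pass. Of 12 genes that act in loading Sm proteins onto snRNA, Gemin2 (-0.91 ± 0.17), Gemin4 (-1.17 ± 0.11), Gemin6 (-1.46 ± 0.23), Gemin7 (-1.06 ± 0.21) and Gemin8 (-1.72 ± 0.24) fell, and Smn1 (0.81 ± 0.10), Clns1a (0.56 ± 0.12) and Ddx20 (0.27 ± 0.10) rose. Of the genes that passed, Snrpd3, Ddx20 and Clns1a did so in 12, 10 and 15 of 17 other settings and the rest in all, and of those that did not, Snrpf passed in 5 and the others in 1 or 2. Gemin5 (-0.09), Prmt5 (-0.19), Strap (-0.17) and Wdr77 (-0.16) did not pass, and no difference between the groups was tested. With mitochondrial scaling Snrpe alone of these 20 genes was called higher (0.53), and Snrpb (0.29), Snrpd1 (0.08), Snrpd2 (0.40), Smn1 (-0.04) and Clns1a (-0.29) did not pass. Snrpd3 and Ddx20 were then called lower (-0.48 and -0.58, edgeR, Benjamini-Hochberg adjusted p = 0.0460 and 0.00853), as were Snrpn and the 9 other loading genes. Among 3' end factors, of which 10 rose and 9 fell, the subunits of CPSF and of CstF went both ways. Of CPSF, Cpsf2 (-0.97 ± 0.14), Cpsf3 (-0.94 ± 0.15) and Fip1l1 (-0.60 ± 0.12) fell, Cpsf4 (0.74 ± 0.13) rose, and Cpsf1 (0.26) and Wdr33 (0.19) did not pass. Of CstF, Cstf2 (-1.26 ± 0.12) and Cstf3 (-0.78 ± 0.17) fell, Cstf2t, an intronless copy of Cstf2, rose (0.65 ± 0.09), and Cstf1 (0.13) did not pass. Pcf11 (-0.85 ± 0.10) fell and its partner Clp1 (0.10) did not pass. Of cleavage factor I, Cpsf6 (0.52 ± 0.11) and Cpsf7 (0.40 ± 0.10) rose, in 16 and 15 of the 17 settings, and Nudt21 (-0.06) did not pass. With mitochondrial scaling Cpsf4 (-0.09), Cstf2t (-0.20) and Cpsf6 (-0.35) did not pass, and the other 12 were called lower.

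Of 127 tested genes of small nucleolar RNAs (snoRNAs), which guide modification of ribosomal RNA, 64 rose and 63 did not pass by edgeR's quasi-likelihood test, with a median log2 fold change of 1.25, and with mitochondrial scaling 29 rose and 3 fell with a median of 0.42. DESeq2 called 53 higher. With counts divided by 4, 71 were tested and 60 rose. Reads of an intronic snoRNA cannot be separated from those of its host in these counts. Pseudogenes matched in RefSeq rose in 133 and fell in 40 of 886 cases, with a median of 0.25. At 0 h, 57 tested genes were at 0 in both libraries, and at 5 h 63 were.

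Labelled RNA of short genes was higher and that of long genes lower relative to the median gene. The tables argue against expression level as the whole cause, since rho between log2 fold change and length stayed negative in each of 4 expression classes of protein-coding genes by mean CPM, with -0.189 as the weakest and -0.423 as the strongest. More carry-over of unlabelled, long-lived RNA in the 5 h libraries could raise short, abundant transcripts. A list of 30 long-lived mRNAs had a median log2 fold change of 0.397, between the bounds set beforehand, and lay at percentile 6.25 of lists matched on length and expression, so it did not decide the matter. The immediate early genes, whose mRNAs are short-lived, had a median of 1.03 and a lower quartile of 0.70, which carry-over would not give, so that part of the rise needs another explanation. Earlier termination of long genes without U1 snRNP remains a hypothesis, as do differences in labelling, and neither was tested.

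The 23 tested genes of the repair list had a median span of 63.2 kb, so the fall of the list could follow from length. Their median of -0.94 lay at percentile 0 of 10000 lists matched on length and expression, whose medians ran from -0.39 to 0.24 at the 2.5 and 97.5 percentiles, which argues against gene span as the whole cause. Lists of SR proteins, hnRNPs, immediate early genes, ribosomal proteins and snoRNA hosts lay at percentile 99.99 or above of their matched lists. The p53 targets lay at 97.9, just outside the middle 95% of theirs (a median of 0.538 against an upper bound of 0.529). Neuroectoderm and epiblast genes, at 97.53, and nuclear long non-coding RNAs, at 2.39, also lay just outside. The U1, U2 and Pol II elongation lists lay at 96.3, 86.5 and 78.1, within the middle 95% of theirs, as did heat shock genes at 60.1. The histones lay at 0 (a median of 0.60 against 0.83). Intron number, GC content and reads shared with other genes stay open. A specific effect of SNRNP70 loss on repair genes is a hypothesis that the 2 groups cannot separate from other effects of auxin. If the 0 h cells were wild type, as their labels say, it could not be separated from a difference between lines either.

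Some of the rises of 8-fold or more could be transcription running on from a strong neighbour into a gene that is itself nearly silent. L3mbtl1, at 2.55 CPM at 0 h, lies beside Srsf6, which had 402 CPM at 0 h and 844 CPM at 5 h. Of 116 genes with such rises, 80 had a position. Of these, 30 (37.5%) had a tested neighbour within 10 kb with at least 20 CPM and 10 times their own level at 0 h. Many of the 80, Cyp1a1 among them, had 0 counts in both 0 h libraries. Their fitted rises rest on no 0 h count (Cyp1a1 was at least 4.32-fold higher), and any neighbour of 20 CPM met the ratio. Genes matched on 0 h level had 41.9% on average and 51.2% at the 95th percentile of 10000 draws. Since 69.0% of the genes had a position, too few for the test to count, and strand was not known, run-on and activation of the genes themselves cannot be told apart.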
